A study of Arabidopsis thaliana with 12 samples.

How the data were processed

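Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on 14-day-old Arabidopsis thaliana Col-0 seedlings grown under 16 h light and 8 h dark at 22 °C. The 12 samples comprised wild type and the val1val2 double mutant precipitated for trimethylated lysine 27 of histone H3 (H3K27me3), VAL1-GFP in val1 and VAL2-GFP in val2 precipitated for the tagged protein, each with 2 replicates, and 4 inputs. Each genotype or tagged line had a single input. VAL1 and VAL2 are transcriptional repressors with a B3 DNA-binding domain. Peak lists of 7 samples were analysed, 2 per H3K27me3 genotype, 2 for VAL1-GFP and 1 for VAL2-GFP. The list of the second VAL2-GFP sample and the RNA-seq named by the series type were not analysed here, and the inputs entered no comparison of their own.

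Each list was called by the authors on its own sample with MACS2, against the TAIR10 build, per the submitters' processing notes. Those notes also named TopHat2 2.1.1, Cufflinks 2.2.1 and Cuffdiff without saying which data each was used on. The MACS2 version, the aligner of the ChIP reads, the control behind each list and the calling options are not given in the sources used here. The deposited pileup column is a signal of read coverage, the deposited fold enrichment is a ratio over the local background that MACS2 estimated, and the deposited significance columns are −log10 p and −log10 q. The headers of the significance columns held a spreadsheet error, so they were read by the MACS2 column order; the column read as −log10 q never exceeded the column read as −log10 p. The H3K27me3 lists held broad regions without summits, and the GFP lists narrow peaks with 1 line per summit. Fold enrichments quoted for single peaks are the authors' own values. They were used to rank or filter peaks within a list and to describe peaks, also side by side between genotypes. They apply to whole peaks, whose widths can differ between lists. With pileup they also gave an implied local background, compared only within a library.

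Coordinates are 1-based positions on TAIR10. The reference sequence and annotation were those of TAIR10.1, and the end of every peak lay within the length of its chromosome, the last one on chromosome 1 at 30427210 of 30427671 bp. Peaks were matched to 27444 protein-coding genes on the 5 nuclear chromosomes. Within a library, overlapping peaks were merged. A gene was called marked by H3K27me3 in a library when peaks covered at least 20% of it from transcription start to end. Genes marked in both wild-type libraries and in neither val1val2 library were called lost, and the reverse gained. A domain was an interval of at least 200 bp covered in both libraries of a genotype, and it was absent from the other genotype when no peak there overlapped it by 1 bp or more. A gene was called bound when a summit lay between 1 kb upstream of its start and its end, in both lists for VAL1 and in the single list for VAL2. A wild-type domain was called VAL1-bound when a summit shared by both lists lay within it or within 1 kb of it.

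Calls rested on overlap, since peak lists hold no counts for a model of each gene. With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.333, so no p was given for differences between genotypes in covered length, and the same calls in the 2 other ways of splitting the 4 libraries served as background. Associations over genes or domains were tested with Fisher's exact test, two-sided, with 95% intervals of the odds ratio. Genes and domains are not independent replicates, because neighbours share peaks. Overlaps of peak sets were therefore also compared with 100 circular shifts along each chromosome, for which the smallest possible p is 0.0099. The shifts keep the spacing of peaks but not their position relative to genes. The labels do not say that replicates came from separate plants, so the spread between replicates may be technical, and the p-values, which run over genes, domains or summits, do not cover variation between plants. At matched peaks the variance of pileup between replicates was 1.22 times counting noise in wild type (5950 peaks) and 1.26 times in val1val2 (6944 peaks), against 8.99 times for VAL1-GFP (1884 peaks), with an assumed fragment length of 200 bp. The RY core, TGCATG or CATGCA on the other strand, was sought within 100 bp of summits and in windows of the same size 1 kb to each side, compared by an exact sign test. Shares carry exact binomial intervals (Clopper-Pearson), which cover counting error only. Depth per sample is unknown, because the lists give no read totals.

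Before the data were examined, 9 gene lists with 96 genes were fixed: seed maturation regulators, seed storage and oleosin genes, flowering time, floral organ identity, meristem and KNOX, phase change, auxin, Polycomb and VAL genes, and housekeeping genes. All 96 identifiers matched the annotation. The values of 1 member are not reported here, although the list counts include it. Each list was tested against all other protein-coding genes, with Benjamini-Hochberg adjustment at 0.05 over the lists within each call; microRNA genes were counted but not tested. Genes were named by a rule fixed at the same time. It took the list members, the 10 lost and 10 gained genes whose H3K27me3 peak ranked highest by fold enrichment within its lists, the 10 genes ranked highest for VAL1, and the 10 lost genes in VAL1-bound domains ranked highest for VAL1. Genes with a symbol came first and 1 gene was taken per peak. Further genes of families described under the other observations were chosen after their values were seen.

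Alternatives were stricter peaks (−log10 q of at least 10), an equal number of peaks per list, other gene cover, overlap and binding windows, and leaving out each replicate. A threshold of −log10 q of at least 2, a strong-peak against no-peak comparison in the deposited lists and in lists of equal length, other thresholds and a narrower background at each threshold for the gene lists, and single VAL1 lists at the stricter threshold were chosen after seeing the data. The scripts were tested on simulated lists over 27444 genes, in which 95.5% of 179 planted losses and 96.8% of 219 planted gains were recovered with 12 false calls of each kind, and a planted odds ratio of 2.19 was found as 2.24. The simulated lists all came from a single wild-type list, with whole peaks removed or added and the same summits in every VAL list. They check the scripts and do not give the error rate of calls on the real lists. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.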

Results

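Peak lists from 14-day-old seedlings recorded where H3K27me3, the histone mark of Polycomb repression, lay in wild type and in val1val2, and where GFP-tagged VAL1 and VAL2 were bound. The 2 wild-type lists held 8324 and 8325 H3K27me3 peaks over 17.5 and 17.8 Mb, and the 2 val1val2 lists 9925 and 10024 peaks over 19.2 and 19.3 Mb. The 2 VAL1-GFP lists held 16637 and 23773 peaks with 21580 and 34554 summits, and the VAL2-GFP list 20275 peaks with 30493 summits. Read depth was unknown. The lists reached down to weak peaks: between 76.7% and 81.1% of the H3K27me3 peaks, and between 29.8% and 54.4% of the summits, had a q of 0.01 or less. The replicate lists of wild type shared 87.0% of their combined covered length and those of val1val2 85.8%, against 34.1% for VAL1-GFP.

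The first comparison asked where H3K27me3 differed between wild type and val1val2. AGL15, a MADS-box gene that promotes embryonic identity, was covered by H3K27me3 over 88.6% ± 2.39 (SD, n = 2) of its length in wild type and had no peak in val1val2. SESA3, a gene for a 2S albumin seed storage protein, was covered over 100% in both wild-type libraries and not at all in val1val2, and OLEO3, an oleosin of seed oil bodies, went from 85.0% ± 0.645 (SD, n = 2) to 0. Of the microRNA genes of the juvenile phase, MIR156C went from full cover to 0. MIR156A kept full cover under a shorter peak, of 1452 and 1534 bp in val1val2 against 4726 and 4725 bp in wild type. SPL9, a target of miR156 that promotes the adult phase, had no peak in wild type and 95.3% ± 0.904 (SD, n = 2) cover in val1val2. VAL1 itself (AT2G30470, annotated as HSI2) was covered over 42.3% ± 0.889 (SD, n = 2) in val1val2 and VAL2 (AT4G32010, HSL1) over 24.5% ± 1.29, both from 0 in wild type. Both genes are mutated in val1val2, and whether the mutant alleles themselves give rise to these peaks was not tested.

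The 10 lost genes with the strongest wild-type peaks were SUT4, a sucrose transporter gene, RIC6, which encodes a ROP-interacting protein, PRR1, a pinoresinol reductase gene, AGL15, AUR2, which encodes an Aurora kinase, LCV3, IDH-III, which encodes an isocitrate dehydrogenase subunit, the cold-regulated COR27, BZIP61, and CYP94C1, of jasmonate breakdown. RIC6 went from 96.9% ± 0.712 (SD, n = 2) cover to 0 and BZIP61 from 81.0% ± 0.945 to 0. PRR1 kept 18.7% ± 0.305 of cover in val1val2 and AUR2 kept 13.4% ± 0.1997, each below the 20% needed for a call. The peaks of SUT4 had fold enrichments of 4.94 and 4.65, the highest of the set. All 10 were bound by VAL1 and by VAL2, though PRR1 only at weaker summits (−log10 q of 2.76 and 3.64 for VAL1 and 1.08 for VAL2).

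The 10 gained genes with the strongest val1val2 peaks were NRP1, FLA16, which encodes a fasciclin-like arabinogalactan protein, SK18, a SKP1-like gene, the calcium-dependent kinase gene CDPK9, the expansin gene EXPA20, HB30, which encodes a zinc finger homeodomain protein, EMS1, a receptor kinase gene of anther development, VAL1, the proton pump gene HA9, and VAL2. NRP1 and SK18 went from no peak to full cover in both val1val2 libraries, and HB30 from 0 to 80.6% ± 0.162 (SD, n = 2). Of these 10 genes 5 were bound by VAL1 and 9 by VAL2. The counts include each factor at its own gene, where reads of the GFP transgene may add to the signal. The new peak in VAL1 spanned 12980645 to 12982667 on chromosome 2 in replicate 1, the 3′ part of the gene (12980428 to 12985277, minus strand). That in VAL2 spanned 15483659 to 15485178 on chromosome 4, at its 3′ end (15479379 to 15485354, plus strand).

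**Figure D1:**
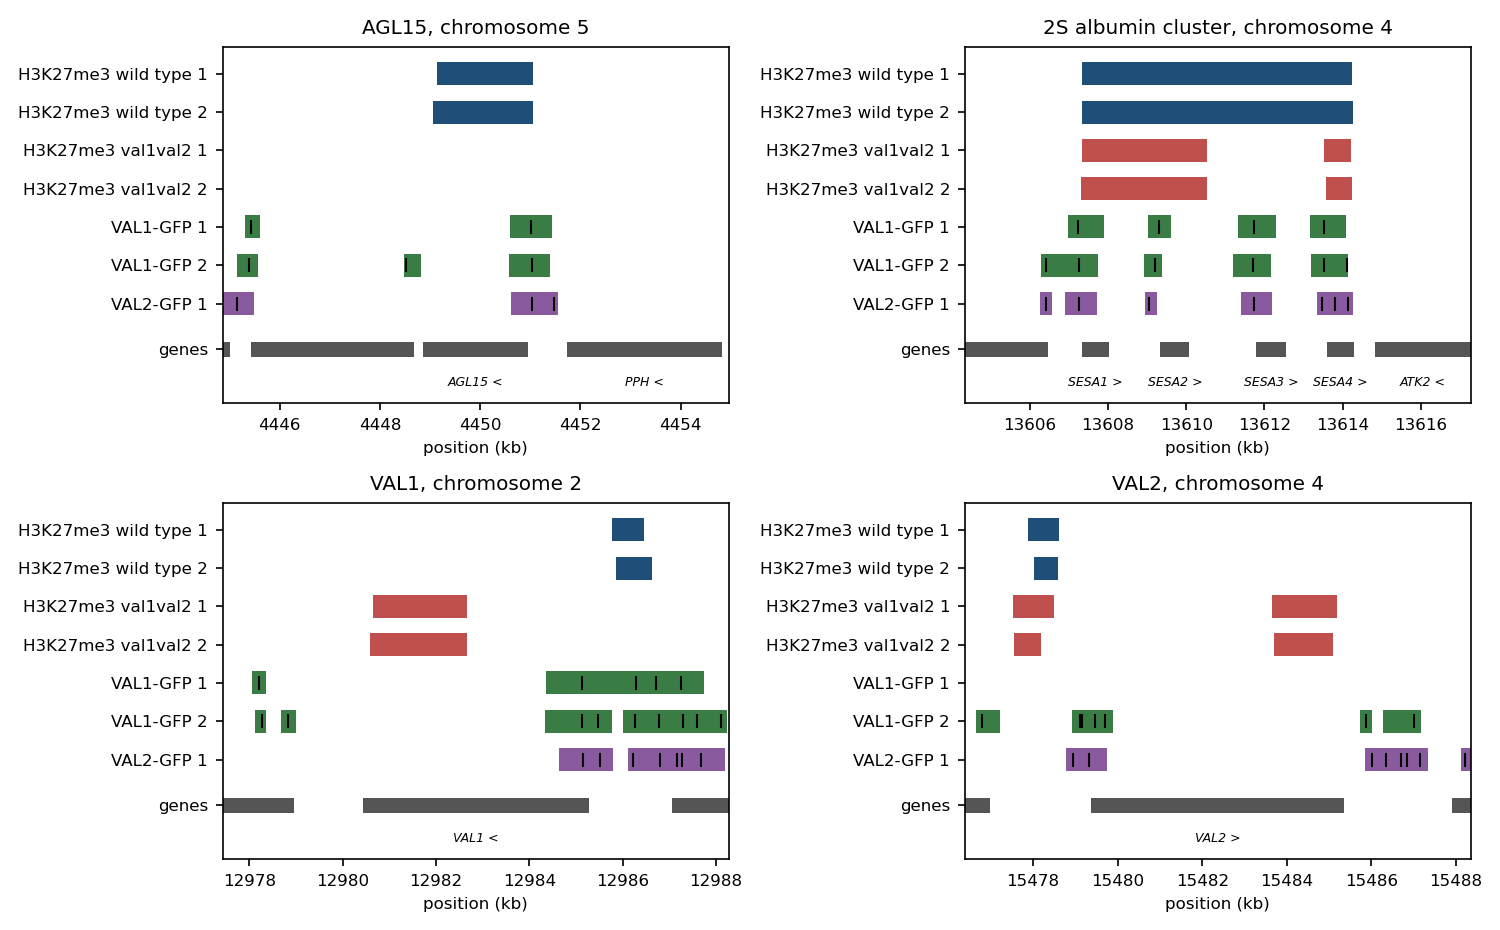
Peaks at AGL15, the 2S albumin cluster, VAL1 and VAL2, with position in kb on the x axis and 1 row per library; boxes are peaks, black ticks are summits, and arrowheads beside gene names give the strand. The wild-type peak over AGL15 (4449136 to 4451043 in replicate 1) has no counterpart in either val1val2 library, and the peak over SESA1 to SESA4 has a gap over SESA3.

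The 2S albumin genes SESA1 to SESA4 lay under a single wild-type peak on chromosome 4, at 13607329 to 13614246 in replicate 1. In val1val2 replicate 1 it was replaced by peaks at 13607323 to 13610539, over SESA1 and SESA2, and at 13613518 to 13614206, over SESA4. SESA3 (13611796 to 13612563) lay in the gap in both val1val2 libraries. Of the 12 seed storage and oleosin genes 11 were marked in wild type (adjusted p = 8.45e-06, Fisher's exact test). SESA3 and OLEO3 were lost, 8 were kept, and OLEO4 was marked in only 1 val1val2 library, with 83.8% ± 0.397 (SD, n = 2) cover in wild type and 20.2% ± 11.8 in val1val2. OLEO1 was kept with 57.3% ± 2.53 cover against 88.9% ± 3.57 in wild type (SD, n = 2). The 2 losses did not pass the test of the list (adjusted p = 0.213, Fisher's exact test). That call depended on the peak threshold: with equal numbers of peaks, 3 members were lost (OLEO4, SESA3 and OLEO3; adjusted p = 0.0353), and at −log10 q of at least 10, 7 were lost (CRU2, OLEO4, OLEO1, SESA3, SESA4, OLEO3 and SESA5; adjusted p = 1.31e-07, both by Fisher's exact test). Among genes marked in wild type alone, the adjusted p of these losses was 0.981 with equal numbers of peaks and 0.0357 at the stricter threshold (Fisher's exact test). Of these 7 genes all but SESA3 and OLEO3 still had val1val2 peaks below that threshold in the deposited lists. Those of CRU2 had −log10 q of 4.60 and 4.70. Those of SESA4 had 7.57 and 9.80 but were not weaker by fold enrichment, with 2.395 and 2.571 over 689 and 671 bp, against 1.616 and 1.593 over 6918 and 6932 bp in wild type.

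Of the 8 seed maturation regulators 7 were marked in wild type (adjusted p = 0.00074, Fisher's exact test), AGL15 was lost and the other 6 were kept (loss of the list, adjusted p = 0.526). LEC2, FUS3 and ABI3, master regulators of seed maturation, had covers of 96.3% ± 0.0705, 100% and 79.9% ± 1.19 in wild type and of 100%, 100% and 71.6% ± 0.889 in val1val2 (SD, n = 2). LEC1, a further master regulator, had 27.9% ± 1.43 and 30.5% ± 0.341. DOG1, a regulator of seed dormancy, had 66.4% ± 1.83 in wild type and 56.2% ± 5.11 in val1val2. The peak over DOG1, which reached beyond the gene in wild type, shortened more, from 4215 and 4195 bp to 1249 and 1098 bp. At −log10 q of at least 10 the lost members were FUS3, AGL15 and DOG1 (adjusted p = 0.00601 against all genes but 0.493 among genes marked in wild type, Fisher's exact test). FUS3 and DOG1 still had val1val2 peaks there, with −log10 q of 5.60 and 5.15 for FUS3 and 4.216 and 3.395 for DOG1, and FUS3 stayed fully covered. By fold enrichment these peaks were similar to those of wild type. The values were 1.94 and 1.91 against 1.874 and 1.841 for FUS3, and 1.974 and 1.854 against 1.966 and 1.926 for DOG1.

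Of the 12 flowering time genes 9 were marked in wild type (adjusted p = 0.00074, Fisher's exact test). MAF5 was lost, from 68.3% ± 6.79 to 0, and its relative MAF3 gained, from 0 to 87.3% ± 0.482 (SD, n = 2), a gain not kept at the stricter thresholds or with equal numbers of peaks. FLC, the floral repressor silenced by vernalization, had 86.0% ± 0.175 cover in wild type and 81.6% ± 2.16 in val1val2. SVP, another floral repressor, had 45.6% ± 2.31 and 91.7% ± 0.0831. Its peaks had −log10 q of 0.938 and 1.88 in wild type and of 19.7 and 19.4 in val1val2, so that at −log10 q of at least 2 or 10 it was called gained, the only gain of the list there (adjusted p = 1.0 and 0.992, Fisher's exact test). All 12 floral organ identity genes (adjusted p = 3.52e-07) and all 13 meristem and KNOX genes (adjusted p = 1.8e-07, Fisher's exact test) were marked in wild type. With the deposited lists only CUC1 of these, which sets organ boundaries, was lost, from 67.0% ± 27.1 to 0, while AG, STM and WUS had means of 91.1% or more in each genotype. STK, of ovule identity, had 89.7% ± 6.04 cover in wild type and 51.03% ± 9.34 in val1val2. At −log10 q of at least 10 the flowering time list, with FT, MAF4 and MAF5, and the floral list, with SEP3, AP1 and FUL (annotated as AGL8), had 3 lost members each (adjusted p = 0.0108 for both against all genes but 1.0 for both among genes marked in wild type, Fisher's exact test); except for MAF5, which had none, these genes kept weaker val1val2 peaks below that threshold.

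Of the 5 phase change genes MIR156C was lost and SPL9 and SPL15 were gained, SPL15 from 0 to 45.7% ± 7.26 (SD, n = 2). MIR156A was kept, with full cover in all 4 libraries, and SPL3 was unmarked. The val1val2 peaks over MIR156A ended at 10676874 and 10676858, before the VAL1 summits at 10676957 and 10676971, which the wild-type peaks included. Their −log10 q was 3.62 and 4.67, against 10.01 and 11.05 in wild type. Fold enrichment was similar, at 1.71 and 1.82 in val1val2 against 1.801 and 1.803 in wild type. The gain of 2 of the 3 SPL genes did not pass after adjustment (adjusted p = 0.107, Fisher's exact test), and the gain of SPL15 was not kept at −log10 q of at least 10. Of the 10 auxin genes 8 were marked in wild type (adjusted p = 0.00074, Fisher's exact test). Only PIN3, an auxin efflux carrier gene, was gained, from 0 to 29.2% ± 0.701, again not at the stricter threshold. The auxin synthesis gene YUC4 was kept with 34.4% ± 1.95 cover (SD, n = 2), against 100% in both wild-type libraries. Of the 17 Polycomb and VAL genes 3 were marked in wild type (MEA, FIS2 and EMF1) and the 3 were kept. VAL1 and VAL2, the mutated genes themselves, were the 2 gains (adjusted p = 1.0, Fisher's exact test). The 7 housekeeping genes were unmarked in each library.

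**Figure D2:**
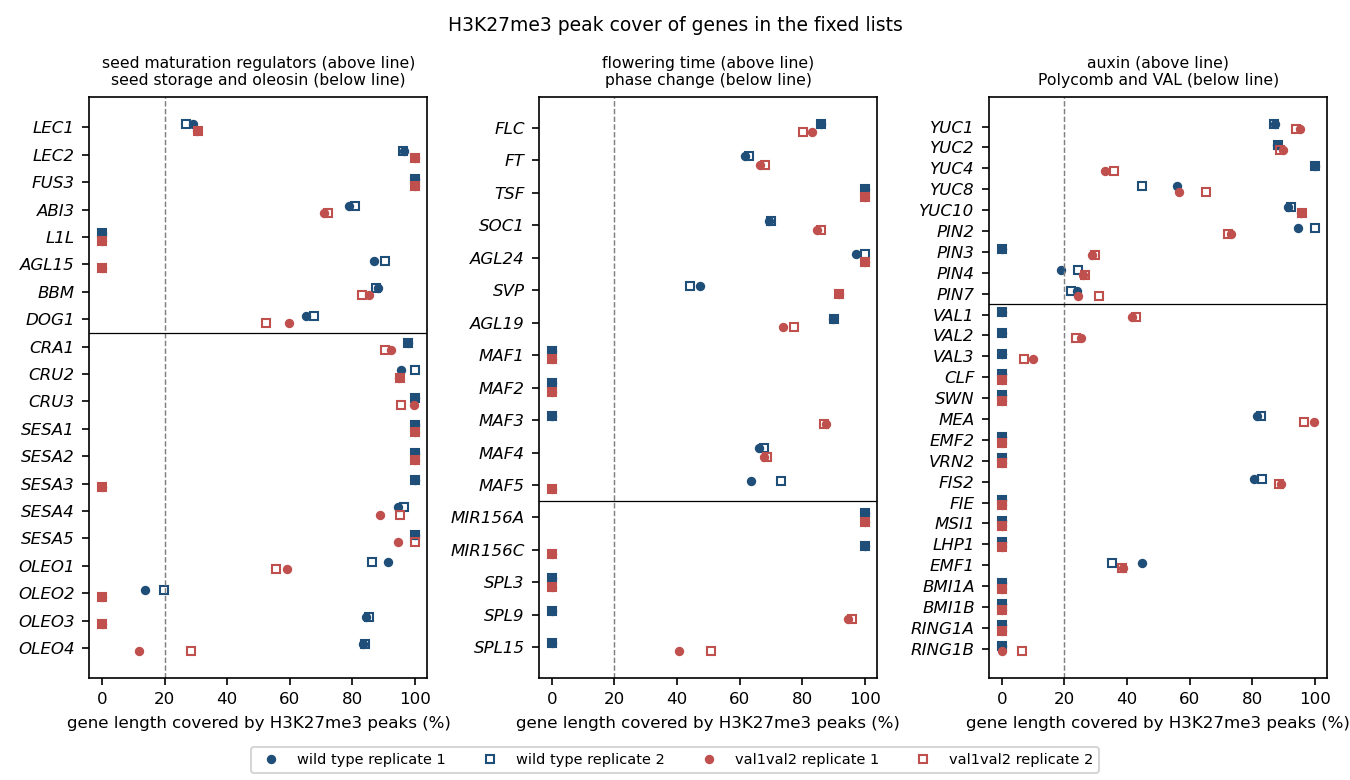
Percent of gene length covered by H3K27me3 peaks (x axis) for genes of 6 fixed lists, 1 gene not being shown, with 1 point per library, in blue for wild type and red for val1val2; the dashed line is the 20% needed for a call. AGL15, SESA3, OLEO3, MAF5 and MIR156C lie at 0 in both val1val2 libraries, and MAF3, SPL9, SPL15, PIN3, VAL1 and VAL2 at 0 in both wild-type libraries.

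Over all genes, 7023 were marked in both wild-type libraries and 8339 in both val1val2 libraries, and 6316 were marked in all 4. The mark was lost from 556 genes, 7.92% of those marked in wild type, and gained by 1763 genes, 8.82% of the 19988 unmarked in wild type. The other ways of splitting the 4 libraries 2 against 2 gave between 8 and 14 genes. That background covers disagreement between replicates only. It does not cover differences between the genotypes in input, depth or plants. Of the 8155 wild-type domains 908 (11.1%) were absent from val1val2, with a median length of 753 bp against 1852 bp for shared domains. Of the 9663 val1val2 domains 2236 (23.1%) were absent from wild type, with a median length of 739 bp. Covered length was 17.6 Mb ± 0.228 in wild type and 19.2 Mb ± 0.0649 in val1val2 (SD, n = 2).

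The balance of gains and losses depended on the peak threshold. Losses were 24.0% of the changed genes with the deposited lists (556 lost, 1763 gained), 29.9% at −log10 q of at least 2 (670 and 1571), 35.5% with equal numbers of peaks (764 and 1390) and 47.6% at −log10 q of at least 10 (821 and 903), where covered length was 7.99 Mb ± 0.284 in wild type and 7.63 Mb ± 0.209 in val1val2 (SD, n = 2). At that last threshold 179 of the 556 lost and 277 of the 1763 gained genes were called again. Among genes covered by such strong peaks in both libraries of 1 genotype and by no peak at all in the other, 142 had lost and 225 had gained the mark, and 192 and 225 when no peak was judged on equal numbers of peaks. With equal numbers of peaks, 1323 wild-type domains were absent from val1val2 and 1386 val1val2 domains from wild type.

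The second comparison asked where VAL1 and VAL2 were bound. The strongest VAL1 peak among named genes lay in an intron of NAC074, a NAC transcription factor gene, with fold enrichments of 18.7 and 35.7 in the VAL1 lists and 19.5 in the VAL2 list. CKX5, a cytokinin oxidase gene, had 15.2 and 29.0, and the other 8 of the top 10 were VGDH1, a pectin methylesterase gene, GER3, which encodes a germin-like protein, CLE41, a peptide signal gene of vascular stem cells, M17, a late embryogenesis abundant protein gene, UMAMIT36, the D-type cyclin gene CYCD1;1, OLEO1 and DOG1. All 10 were bound by VAL2, and all 10 had a lower mean H3K27me3 cover in val1val2 than in wild type. How often other marked genes had lower cover was not computed, and genes at 100% could only fall. Fold enrichments of the remaining peaks fell at CKX5, GER3, UMAMIT36 and OLEO1 and changed little at VGDH1 and DOG1. They were higher at CLE41 and at M17 (2.09 and 2.26 to 3.28 and 2.80), where the val1val2 peaks were shorter. Those of CLE41 spanned 748 and 1175 bp against 4085 and 4189 bp in wild type. Those of M17 spanned 1359 and 2161 bp against 5591 and 2787 bp, so the higher values need not mean more of the mark. At NAC074 the listed values, 1.49 and 1.47 in wild type and 1.89 and 1.84 in val1val2, belonged to peaks that did not overlap. They give no change of a single peak. In cover, CLE41 went from 100% to 57.4% ± 0.906 and NAC074 from 75.6% ± 3.28 to 36.4% ± 4.26 (SD, n = 2). Of these 10 genes 9 were called kept, and CYCD1;1 was called lost, from 23.8% ± 3.32 to 0, a call not kept at the stricter thresholds. At −log10 q of at least 10 neither CLE41 nor NAC074 nor CYCD1;1 was covered in either genotype, so these 3 differences rest on weaker peaks.

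VAL1 bound 10473 genes in both lists and VAL2 14648 genes in its list. Among the fixed lists, VAL1 bound 11 of the 12 seed storage and oleosin genes (adjusted p = 0.00175, Fisher's exact test), 3 of the 8 seed maturation regulators (ABI3, AGL15 and DOG1), 5 of 12 flowering time, 5 of 12 floral, 6 of 13 meristem and KNOX, 4 of 5 phase change, 7 of 10 auxin, 9 of 17 Polycomb and VAL and 2 of 7 housekeeping genes. None of the other lists passed for VAL1 (lowest adjusted p = 0.227, Fisher's exact test), and no list passed for VAL2, which bound 8 of the 12 storage genes and 5 of the 7 housekeeping genes in the deposited list. VAL1 was bound at its own gene with fold enrichments of 5.17 and 10.5, although reads of the VAL1-GFP transgene may fall at the same place. The same limit holds for the VAL2-GFP signal at VAL2. At −log10 q of at least 10 the binding calls fell to 910 genes for VAL1 and 1867 for VAL2. There the seed maturation list passed for both factors with ABI3, AGL15 and DOG1 (adjusted p = 0.00808 for VAL1 and 0.0407 for VAL2, Fisher's exact test). The storage list also passed for both, with OLEO1, SESA1, SESA3, SESA4 and OLEO3 (adjusted p = 0.000233 for VAL1 and 0.00689 for VAL2, Fisher's exact test). For VAL2 alone the housekeeping list passed too, with GAPC1, ACT2 and UBQ10 (adjusted p = 0.0402, Fisher's exact test).

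The RY element, the sequence that B3 domains of this family bind, was more frequent at VAL1 summits than beside them, though most summits had none. An RY core lay within 100 bp of 44.5% (95% interval 43.6 to 45.4%) of the 12038 summits shared by both VAL1 lists, against 8.69% in flanking windows, a ratio of 5.12. From the weakest to the strongest of 5 classes of VAL1 summits the share was 20.5, 28.5, 37.8, 53.4 and 82.3%. At AGL15 the VAL1 summits lay 54 and 71 bp upstream of the transcription start, with the nearest core, TGCATG, at 4451006 to 4451011 on chromosome 5, 20 bp from the summit of replicate 2. It lay within AATGTTGTGTGTTGCATGGCCACTGTTTTG. At SESA3 the window held 6 cores, with overlapping matches within a repeat counted separately. The sequence at 13611701 to 13611730 on chromosome 4 was CACACACTCATGCATGCATGCATTCTTACA. In NAC074 it was TGCGGTCTCGTGCATGCAAATGACCAAACA, at 14091395 to 14091424.

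**Figure D3:**
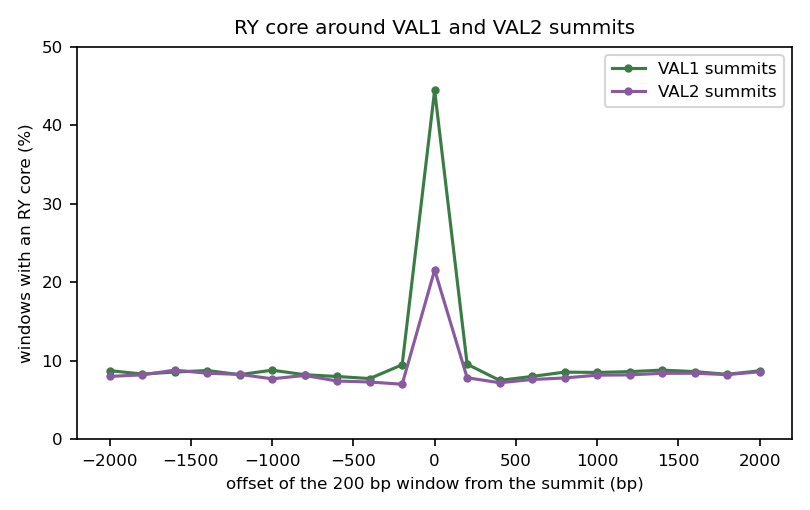
Share of windows of 200 bp with an RY core (y axis, %) by offset of the window from the summit (x axis, bp), for VAL1 summits shared by both lists (green) and VAL2 summits (purple). At the summit the shares are 44.5% and 21.6%, against 8.69% and 7.96% in the windows 1 kb to each side.

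Most VAL1 sites were also VAL2 sites, while VAL2 lay at many further places. Of the VAL1-bound genes 81.1% were bound by VAL2, against 36.3% of the others (odds ratio 7.54, 95% interval 7.12 to 8.00). Of the shared VAL1 peaks 76.5% overlapped a VAL2 peak, against a mean of 17.9% ± 0.963 (SD) and at most 19.9% over 100 circular shifts (permutation p = 0.0099, the smallest they can give). Because the shifts do not keep position relative to genes, they cannot separate shared sites from a common preference for gene starts. Of the 20275 VAL2 peaks, 6653 had their summit inside peaks shared by both VAL1 lists and 6116 outside the peaks of either list. The RY share at the summit was 48.0% inside and 5.82% outside, the latter below its flanks at 7.64% (exact sign test, p = 0.000128). Each summit was assigned to a single class of position, with exons taking precedence. The class within 1 kb upstream of a protein-coding gene held 33.0% of the VAL2 summits, against 22.6% of the VAL1 summits and 13.5% of random positions. The VAL2 values rested on 1 list.

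The third comparison asked whether VAL1 lay at genes with H3K27me3 in wild type. ABI3, AGL15, SESA3, OLEO1 and DOG1 were bound and marked, whereas LEC2, FUS3, STM and AG were marked with no VAL1 call. Of the VAL1-bound genes 31.4% were marked, against 22.0% of the others (odds ratio 1.62, 95% interval 1.54 to 1.72, Fisher's exact test p = 1.36e-66). Of the shared VAL1 summits 23.6% lay in a wild-type domain, against 13.8% over the shifts (permutation p = 0.0099, the smallest they can give), and the RY share was 57.4% inside and 40.5% outside such domains. The direction depended on the VAL1 list: it was 1.84 with replicate 1 alone and reversed to 0.902 with replicate 2 alone (Fisher's exact test, p = 0.000292), whereas at −log10 q of at least 10 it was 3.16 and 2.23. For VAL2 the odds ratio was 0.781 with the deposited list and 1.35 at −log10 q of at least 10 (Fisher's exact test, p = 5.32e-19 and 2e-08), and 13.1% of its summits lay in wild-type domains, against 13.7% ± 0.410 (SD) over the shifts (permutation p = 0.941).

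The last comparison asked whether wild-type domains at VAL1 sites lost H3K27me3 in val1val2 more often than others. The 10 lost genes with the strongest VAL1 peaks in such domains were CYCD1;1, LCR61, RIC6, BZIP61, PUB18, which encodes a ubiquitin ligase, SESA3, IAMT1, which encodes an auxin methyltransferase, BZIP34, NIT4, a nitrilase gene, and AtVEX1. LCR61 and NIT4 went from 100% and from 89.3% ± 3.24 cover to 0, and IAMT1 from 98.5% ± 0.518 to 5.27% ± 7.45 (SD, n = 2). All 10 were also bound by VAL2. The losses of CYCD1;1, LCR61, IAMT1 and BZIP34 were not called at −log10 q of at least 10.

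Of the 4171 VAL1-bound domains 646 (15.5%) were absent from val1val2, against 262 (6.58%) of the 3984 unbound ones, an odds ratio of 2.60 (95% interval 2.24 to 3.03, Fisher's exact test p = 1.72e-38). Long domains met more summits and were lost less often, and over classes of domain length the odds ratio was 3.31 (2.82 to 3.89). In the shortest of 5 length classes 36.3% of the bound and 19.3% of the unbound domains were lost, and in the longest 2.10% and 0.414%. Domains bound by both factors were lost in 15.8% of cases and domains bound by neither in 5.22% (odds ratio 3.41, 2.79 to 4.15). Seen from the genes, 74.6% of the 556 lost genes were bound by VAL1, against 44.1% of the 6316 kept genes (odds ratio 3.74, 3.07 to 4.55). Without the 1 kb extension of the domain the odds ratio was 1.45.

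**Figure D4:**
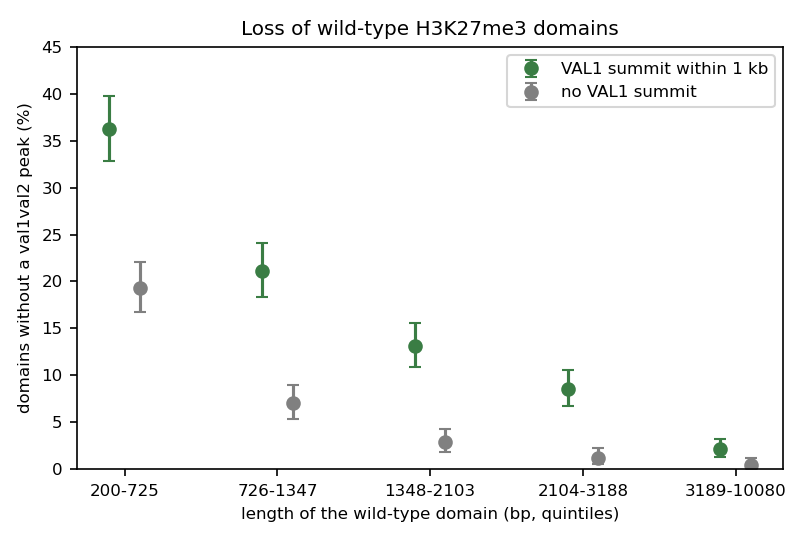
Percent of wild-type H3K27me3 domains absent from val1val2 (y axis) in each of 5 classes of domain length (x axis, bp), for VAL1-bound and unbound domains; bars are 95% binomial intervals. Bound domains were lost more often in each class, from 36.3% against 19.3% in the shortest to 2.10% against 0.414% in the longest.

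No higher frequency of gains was detected at VAL1-bound genes. SPL9 and PIN3 were gained and bound by VAL1, and NRP1, SK18, MAF3 and SPL15 were gained and not bound in both lists. The VAL1 summits recorded at SPL9 and PIN3 differed in place between the lists. They lay 71 bp upstream and 617 bp downstream of the start at SPL9 (−log10 q of 1.85 and 1.80). At PIN3 they lay 343 and 2237 bp downstream (−log10 q of 1.74 and 3.29). Among genes unmarked in wild type, 8.97% of the VAL1-bound and 8.74% of the other genes gained the mark (odds ratio 1.03, 95% interval 0.929 to 1.14, Fisher's exact test p = 0.601). With VAL1 peaks of −log10 q of at least 10 the odds ratio was 0.591 (0.387 to 0.902, 23 of 422 genes), at −log10 q of at least 2 it was 0.975 (0.840 to 1.13), and with VAL2-bound genes 0.809 (0.734 to 0.892).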

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

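The settings at −log10 q of at least 2, the strong-peak against no-peak counts, and the other thresholds and backgrounds for the gene lists were chosen after seeing the data. Of 96 values under other settings 79 kept direction and side of the test or, where there was none, stayed within the spread of covered length or within 1.5 times the count, 15 moved further and 2 reversed; 33 of the 34 values with a test kept direction and call. Counts within that factor still changed: lost genes, 556 with the deposited lists, were 821 at −log10 q of at least 10 and 764 with equal numbers of peaks, and absent wild-type domains went from 908 to 1336 when presence needed 50% of the domain covered. With H3K27me3 peaks of −log10 q of at least 10, gained genes were 903, val1val2 domains absent from wild type 871, and the ratio of covered length, val1val2 over wild type, reversed to 0.955. With equal numbers of peaks those domains were 1386, against 1323 wild-type domains absent from val1val2, and the ratio was 1.02. Genes bound by VAL1 were 910 and by VAL2 1867 at −log10 q of at least 10, 4249 and 9427 at −log10 q of at least 2, and 6631 for VAL1 within 500 bp of the transcription start; the ratio of covered length at −log10 q of at least 2 was 1.07. The lower counts follow from the narrower calls. Strong peaks against no peak gave 142 lost and 225 gained genes, and 15 list tests passed at −log10 q of at least 10 against 7 with the deposited lists; with only genes that could be called as background the count was 12 at that threshold, and of the lists only storage then passed for loss (adjusted p = 0.0357, Fisher's exact test), while none passed for loss or gain in the deposited lists, at −log10 q of at least 2 or with equal numbers of peaks. Leaving out 1 VAL1 replicate gave 12049 to 17056 bound genes and odds ratios of wild-type marking from 0.902 to 1.84; the cause of that reversal and of the reversed length ratio was not tested. Treating replicate numbers as a block (pairing) gave a length ratio of 1.09. Of 36 named genes with a call, 29 kept it at −log10 q of at least 10, 35 with equal numbers of peaks and 34 at −log10 q of at least 2. Unknown depth limits how far absence of a peak can be read as absence of the mark.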

Other observations

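Of the 326 microRNA genes 112 were marked by H3K27me3 in wild type, 17 of which were lost in val1val2, while 16 microRNA genes gained the mark. The lost ones were MIR156c, MIR160b, MIR167d, MIR169b, MIR169f, MIR390a, MIR393a, MIR404, MIR407, MIR420, MIR5635d, MIR5665, MIR826a, MIR826b, MIR829, MIR864 and MIR867. The set of microRNA genes and the gene families below were chosen after the main results were seen.

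Several gene families gained H3K27me3 more often than other genes unmarked in wild type (adjusted over 24 families). F-box genes gained it in 60 of 268 cases (22.4% against 8.64%, Fisher's exact test, adjusted p = 2.63e-10). Disease resistance genes with a nucleotide-binding site gained it in 26 of 100 (Fisher's exact test, adjusted p = 4.28e-06). B3 domain genes, the mutated VAL1 among them, gained it in 14 of 43 (Fisher's exact test, adjusted p = 8.83e-05). Genes of the photosystems and chlorophyll-binding proteins gained it in 17 of 67 cases (25.4%, exact test, adjusted p = 0.000249), among them LHCA2, CAB1, CAB2, PSAG and PSAL. The other families that passed were cytochrome P450 (18 of 89, adjusted p = 0.00321), homeobox (11 of 48, adjusted p = 0.00774), seed storage, oleosin and lipid transfer proteins (16 of 88, adjusted p = 0.0116, none of the 16 in the fixed storage list), leucine-rich repeat kinases (23 of 160, adjusted p = 0.0412) and MADS-box genes (10 of 52, adjusted p = 0.0489, all by exact tests). Pentatricopeptide repeat genes gained it less often (7 of 270, exact test, adjusted p = 0.000249), as did ribosomal protein genes (12 of 317, adjusted p = 0.00253). VAL1 bound 53 of the 72 photosystem and chlorophyll-binding genes (odds ratio 4.54, exact test, adjusted p = 9.43e-09) but only 23.2% of the F-box genes (odds ratio 0.481, adjusted p = 4.53e-15). No family passed for loss (lowest adjusted p = 0.172, exact test). The families were tested with the deposited lists only. Of all 1763 gained genes, 277 were called again at −log10 q of at least 10 and 1390 with equal numbers of peaks. Neighbouring members of a family can share a peak, so the genes behind these p-values are not independent.

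The tests of the implied background in wild type, of gains at strong VAL1 peaks and of strong peaks against no peak in lists of equal length were chosen only after the result was seen; those with equal numbers of peaks and over domain length were planned, but what would count against each explanation was set after their values were seen. More genes gained than lost H3K27me3 in val1val2. Longer val1val2 lists stay open as a cause. With equal numbers of peaks gained genes were still 1.82 times the lost ones. That test cannot decide, because val1val2 peaks then still covered more sequence (mean 18.03 Mb against 17.62 Mb in wild type). At −log10 q of at least 10 the lists held 3224 and 3355 peaks in val1val2 and 3121 and 3249 in wild type. There 903 genes were gained and 821 lost. For domains the ratio fell from 2.46 to 1.05 with equal numbers of peaks. Weak peaks stay open: from strong peaks to none the ratio was 1.59, with its interval above the bound set to argue against them, but that bound was wrong because longer lists leave fewer genes with no val1val2 peak and so favour gains there, and with lists of equal length it was 1.17 (95% interval 0.962 to 1.43). A low local input background in val1val2 stays open too, since the background implied by pileup and fold was 0.587 times as high at new as at shared domains, but 0.567 times in wild type for the domains it alone held. Whether gains favour VAL1 sites was undecided over all bound genes (odds ratio 1.03, 0.929 to 1.14) and at −log10 q of at least 2 (0.975, 0.840 to 1.13), was argued against for VAL1 peaks of −log10 q of at least 10 (0.591, 0.387 to 0.902, from 23 of 422 genes), and an effect of the genotype by another route was not tested.

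Wild-type domains at VAL1 sites were lost more often. Domain length alone or weak domains alone would bring the stratified odds ratio to 1, but it was 3.31 over length and 4.27 (3.62 to 5.04) over wild-type −log10 q. Precipitation of open chromatin without sequence recognition, as the source of all VAL1 sites, would give equal loss with and without an RY core. However, bound domains with a core at the summit were lost in 18.3% of cases and those without in 10.8% (odds ratio 1.84, 1.53 to 2.23). Those without were still lost more often than unbound domains (6.58%), so such precipitation stays open for part of the sites. The odds ratio for a core was not stratified by VAL1 peak strength, with which the share of cores rose. A hypothesis that goes with these values is that VAL1 at RY elements may help to keep H3K27me3 at part of its domains. VAL2-bound domains were lost more often too (13.7% against 6.80%, odds ratio 2.18). Since val1val2 is mutant for both factors, their parts cannot be told apart. The hypothesis was found and tested on the same lists, and depth, the control behind each list and separate plants stay unknown.

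VAL2 summits outside VAL1 peaks may partly come from precipitation of open chromatin without sequence recognition. An RY core was 0.762 times as frequent there as in the flanks. The class within 1 kb upstream of genes, with exons counted apart, held 33.3% of these summits, against 13.5% of random positions. Recruitment of VAL2 by other proteins predicts the same values, and neither the second VAL2-GFP sample nor a precipitation from untagged plants was used here, so a biological source was not tested.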
